A study of Homo sapiens with 12 samples.

How the data were processed

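MDA-MB-468 cells were grown in 4 conditions with 3 libraries each: DMSO, docetaxel (10 nM) for 8 h, docetaxel for 24 h, and the combination of tazemetostat (5 µM) and ipatasertib (5 µM). Per the labels, docetaxel was given in 10 cm plates, and the cells of the targeted treatment were held in tazemetostat or DMSO for the 5 days before dosing, moved to 6 cm plates and dosed in medium with 2% FBS for 24 h. The serum of the docetaxel cultures is not stated. RNA was extracted with a column kit, poly(A) RNA was selected with oligo-T beads, and cDNA was primed with random hexamers. The protocol allows a directional or a non-directional library and does not say which was made, so reads of genes that overlap on opposite strands may have been counted together. The labels state neither the hours, the serum nor the plate size of the DMSO libraries, and give no arm for tazemetostat or ipatasertib alone.

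The deposited counts are whole numbers per gene symbol, in a table per library, which the authors made from the sequencing reads. The fastp, HISAT2 2.0.5 and DESeq2 tools and the build hg38 are named per the submitters' processing notes, without their roles. The counting program, the annotation and the strand setting are not given in the sources used here. A further deposited table holds a signal per gene and library that the authors obtained by dividing each library's counts by a size factor between 0.829 and 1.386. Symbols that occur more than a single time were left out of this check, which left 56990 per library. Between 23659 and 26278 of them had a count, all of these fitted the ratio within a relative tolerance of 1e-06, and the rest were 0 in both tables. The design had foreseen that table as a list of docetaxel comparisons, so the planned comparison with the authors' calls could not be made, and its size factors served as an alternative scaling only. Of the 58735 symbols 58708 were matched to GENCODE release 29 (GRCh38, the same build as hg38), from which gene types and coordinates were taken. The other 27 symbols had the form of dates, as spreadsheets make them, and held at most 0.204% of a library's counts. A symbol repeated in the table was kept as separate genes (1745 entries).

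Total counts lay between 29820617 and 45807059 per library. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17780. edgeR 4.0.16 in R 4.3.3 fitted all 12 libraries with a mean per group, TMM factors (0.917 to 1.05) and 8 residual degrees of freedom, and its quasi-likelihood test was run for 5 comparisons, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are those of edgeR's fit with its own default prior count, the log2 CPM of the list tests use a prior count of 2, and normalised CPM use none. A gene with no counts in a group was given a fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% counting interval. PCR copies were not marked, so counts are not all independent molecules.

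There were 27 gene lists, fixed with the named genes before the data were examined. They covered mitosis, replication, p53 targets, tubulins, luminal and basal markers, involution, milk and secretory genes, the BCL2 family, FOXO targets, PRC2 subunits, HOX genes and developmental regulators. They also covered interferon, antigen presentation, NF-kB cytokines, sterol and fatty acid synthesis, glycolysis, ATF4 with the unfolded protein response, immediate early genes, YAP and SRF targets, replication histones and mitochondrial mRNAs. Fibroblast, immune and endothelial markers were included as lists of other cell types. Each list was tested with camera of limma 3.58.1 on log2 CPM, with the preset correlation of 0.01, and again with an estimated correlation and with fry. The p-values of lists were adjusted over the 27 lists of a comparison. For each list the genes past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Some genes sit in 2 lists, such as BMF, IL6, LIF and ELF5.

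Single genes were named by a rule. In each comparison with DMSO the 8 largest rises and the 8 largest falls by fitted log2 fold change were taken, and in the other 2 comparisons 5 of each, among protein-coding genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries. To these were added up to 4 members of each list with the smallest adjusted p and 32 genes fixed by name, among them EZH2, AKT1, GATA3, KRT5, BMF, STAT3 and CDKN1A. Some genes that the rule names are not reported. Genes outside the rule are said to be chosen after their values were seen. The shared response was described by correlations across genes and by overlaps of calls, beside 20 simulations of unchanged groups against the same 3 DMSO libraries. Intervals of list medians came from 10000 bootstrap draws of the genes in a list or set. They treat these genes as independent and do not cover the spread between libraries.

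The test was checked on simulated data in which 200 genes were changed by known folds, 50 per fold, and the genes of the sterol list were lowered together. At 1.25-fold 68% were recovered in the comparison of docetaxel 8 h with DMSO, 66% at 24 h and 62% in the combination, and at 2-fold 94%, 98% and 90%. Of genes left unchanged 11 of 16399, 26 of 16378 and 8 of 16388 were called. The simulations changed far fewer genes than the data did, where 34.9% to 63.8% of genes were called in a comparison. They therefore do not show how scaling, recovery or false calls behave when that many genes change. The alternatives planned were DESeq2 size factors, upper-quartile factors, library totals only, no low-count filter, a filter of CPM of at least 1 in 3 libraries, DESeq2's Wald test (1.42.0), limma-voom, fits of the 2 groups compared, the letter as a replicate block, protein-coding genes only, each library left out in turn, and a fold threshold. Chosen after seeing the data were the authors' size factors and a fit without mitochondrial genome genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.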

Results

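Messenger RNA was sequenced from MDA-MB-468 cells, a triple-negative breast cancer line, in 12 libraries that the labels place in 4 groups of 3: vehicle (DMSO), 10 nM docetaxel for 8 h, 10 nM docetaxel for 24 h, and 5 µM tazemetostat with 5 µM ipatasertib for 24 h (the combination). Docetaxel is a taxane that stabilises microtubules. Tazemetostat inhibits EZH2, the methyltransferase of Polycomb repressive complex 2 (PRC2), and ipatasertib inhibits the kinase AKT. Before the 24 h, the cells of the targeted treatment had been held in tazemetostat or DMSO for 5 days. Exposure to tazemetostat may therefore have been longer than 24 h. The total counts of libraries A, B and C were 41512254, 30654888 and 32619948 in DMSO and 36831143, 34054504 and 30205713 at 8 h of docetaxel. They were 32685186, 31475791 and 45807059 at 24 h and 32732377, 30249164 and 29820617 in the combination. The 4 groups allowed 5 comparisons: each treatment with DMSO, the docetaxel time points with each other, and the combination with docetaxel at 24 h. They ask which genes change under each treatment, how the docetaxel response moves between 8 h and 24 h, and how the targeted combination differs from chemotherapy.

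Values of single genes are given as CPM, counts scaled to a common library size with TMM factors, with the SD over n = 3 libraries. Log2 fold changes are followed by ± an approximate SE, the size of the fold change divided by the square root of the test's F statistic. The biological coefficient of variation over all libraries was 5.59%, and 17780 genes were tested. Coordinates are on GRCh38, from GENCODE release 29. The main axis of variation, 68.1% of the variance, set the combination apart from the other 3 groups. Replicates differed from each other by more than sampling noise, with a chi-square per degree of freedom between 3.24 and 16.2 over the pairs of libraries within a group. The labels do not say that the letters A, B and C stand for separate cultures, so p-values measure the spread between these libraries, which may be technical. Genes of the mitochondrial genome took 4.21% ± 0.244 (SD) of the counts in DMSO, 8.55% ± 0.409 at 8 h of docetaxel, 6.38% ± 1.28 at 24 h and 8.49% ± 0.799 in the combination, n = 3 libraries each. The medium, the plate size and the hours since dosing of the DMSO libraries are not stated, and no vehicle was labelled as collected at 8 h. The protocol describes vehicle cells for the targeted treatment only, and does not say which treatment the DMSO libraries belong to. Differences of docetaxel from DMSO may therefore also be differences of plate, medium or days of culture.

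At 8 h of docetaxel, most genes of sterol and fatty acid synthesis were lower than in DMSO, while most genes of mitosis and the basal keratins were higher. HMGCS1 (chromosome 5, 43289395 to 43313512), which makes the precursor of mevalonate, fell from 407 ± 10.1 to 165 ± 8.69 CPM, a log2 fold change of -1.30 ± 0.05. SCD (chromosome 10, 100347124 to 100364834), the desaturase that makes monounsaturated fatty acids, fell from 1807 ± 43.5 to 662 ± 26.1 CPM (-1.45 ± 0.05). KRT17 (chromosome 17, 41619441 to 41624842), a keratin of basal and wounded epithelium, rose from 565 ± 1.45 to 1633 ± 80.01 CPM (1.53 ± 0.06). Among protein-coding genes of at least 5 CPM in the higher group and without overlap between the libraries, the rule by which single genes are ranked throughout, the largest rise was that of CYP1A1 (chromosome 15, 74719542 to 74725610), the classic target of the aryl hydrocarbon receptor, from 1.2499 ± 0.183 to 34.0 ± 2.60 CPM (4.74 ± 0.11). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 4 genes had adjusted p-values of at most 1.29e-14.

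Among the 8 named genes with the largest rises, CYP1B1, a further cytochrome of that receptor's programme, went from 106 ± 5.71 to 320.3 ± 23.8 CPM (1.60 ± 0.06). The others were IGFL1 (3.07 ± 0.11), the keratins KRT6A (2.88 ± 0.17) and KRT75 (2.02 ± 0.16), OLFML3 (2.31 ± 0.08), the matrix protease MMP7 (1.69 ± 0.07) and the neuropeptide gene GAL (1.60 ± 0.10). KRT6A and KRT6B are near-identical, so their counts may be shared and each value is uncertain. The largest falls by the same rule were those of TF, which encodes transferrin, from 20.6 ± 1.55 to 4.65 ± 0.512 CPM (-2.14 ± 0.10), and of NEURL3 (-1.84 ± 0.09), SLC12A3 (-1.81 ± 0.13) and NCMAP (-1.72 ± 0.12). They were followed by the amino acid transporter SLC6A14 (-1.67 ± 0.07), CMYA5 (-1.66 ± 0.11), the transcription factor ETV1 (-1.64 ± 0.15) and LRP1 (-1.60 ± 0.14). All 16 had adjusted p-values of at most 9.78e-09 by edgeR's quasi-likelihood test.

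Of the 25 measured genes of sterol synthesis and uptake, 23 fell and the other 2 did not pass, with the same count adjusted over the list alone and a median log2 fold change of -0.58. Lanosterol synthase (LSS) fell by 1.15 on the log2 scale and DHCR7, the enzyme of the last step, by 0.90. The list had a camera adjusted p = 2.62e-13, against adjusted p = 0.0696 with an estimated correlation. In fatty acid synthesis 14 of 15 genes fell and 1 rose, the same counts adjusted over the list alone (median -0.74; camera adjusted p = 8.10e-08, and adjusted p = 0.0410 with an estimated correlation). FASN, the fatty acid synthase, went from 2217 ± 131 to 1260.0 ± 63.5 CPM (-0.82 ± 0.06). ACSS2 (-0.84 ± 0.05) and ACLY (-0.78 ± 0.05), which supply acetyl-CoA, fell too. In the same libraries all 13 mitochondrial mRNAs rose, with a median of 1.18 (camera adjusted p = 8.10e-08, against adjusted p = 0.248 with an estimated correlation).

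Mitotic genes rose at 8 h: 28 of 30 were higher and the other 2 did not pass, the same adjusted over the list alone (median 0.53; camera adjusted p = 1.92e-14, against adjusted p = 0.0696 with an estimated correlation). The mitotic kinase AURKB went from 62.5 ± 3.34 to 117 ± 9.57 CPM (0.91 ± 0.06). AURKA rose by 0.74 ± 0.05, PLK1 by 0.71 ± 0.05, the ubiquitin-conjugating enzyme UBE2C by 0.93 ± 0.06, cyclin CCNB1 by 0.59 ± 0.05 and the proliferation marker MKI67 by 0.59 ± 0.08. Of 30 replication genes 20 rose and 3 fell, and 21 and 3 adjusted over the list alone (camera adjusted p = 1.22e-05, against adjusted p = 0.0857 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, went from 176 ± 3.14 to 323 ± 12.6 CPM (0.87 ± 0.05), and CDC45, GINS2 and TK1 rose by 0.62, 0.67 and 0.54. Of 15 tubulin genes, which are near-identical in part and so uncertain one by one, 7 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0173, against adjusted p = 0.248 with an estimated correlation). TUBB4B (1.02 ± 0.05), TUBB6 (0.95 ± 0.05), TUBG1 (0.55 ± 0.05) and TUBB (0.56 ± 0.06) rose, whereas TUBA1B stood at 0.09 ± 0.06 and did not pass.

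Basal and luminal markers went both ways, with more basal genes higher than lower and more luminal genes lower than higher. Of 22 basal or myoepithelial genes 13 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.0110, against adjusted p = 0.0857 with an estimated correlation). KRT5 (0.81 ± 0.05), KRT14 (0.66 ± 0.06) and KRT6B (1.09 ± 0.06) were higher. Of 23 luminal genes 5 rose and 13 fell, 5 and 14 adjusted over the list alone (camera adjusted p = 0.0344, against adjusted p = 0.256 with an estimated correlation). The luminal factors GATA3, FOXA1 and XBP1 fell by 0.38, 0.53 and 0.53 on the log2 scale. The epithelial factor EHF fell by 1.19 and MLPH by 0.61, while the luminal keratin KRT18 rose by 0.32 ± 0.07. The keratins KRT7 (0.27) and KRT19 (0.41), chosen after their values were seen, and KRT8 (0.20 ± 0.06) rose too, though KRT8 did not pass with library totals (0.05, adjusted p = 0.440). Among genes of mammary involution, the regression of the gland after weaning, 6 of 26 rose and 12 fell, 6 and 13 adjusted over the list alone (camera adjusted p = 0.0435, against adjusted p = 0.256 with an estimated correlation). IGFBP5 (-1.24 ± 0.05), CD14 (-1.09 ± 0.07), PIK3R3 (-0.57 ± 0.05), the cytokine receptor IL6ST (-0.70 ± 0.06), STAT3 (-0.47 ± 0.05) and SOCS3 (-0.34 ± 0.09) fell. With library totals in place of TMM factors the luminal call ended at camera adjusted p = 0.0576 (range over the 8 alternatives with the preset correlation 0.0233 to 0.0576). The involution call ended with library totals at 0.107 and without docetaxel 8 h library B at 0.0564 (range 0.0235 to 0.107).

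Genes that FOXO factors activate fell at 8 h: 18 of 27 were lower and 1 was higher, the same adjusted over the list alone (median -0.35; camera adjusted p = 3.88e-06, against adjusted p = 0.0941 with an estimated correlation). FOXO3 (-0.73 ± 0.06), the receptor ERBB3 (-0.65 ± 0.05), KLHL24 (-0.70 ± 0.06) and PIK3IP1, an inhibitor of phosphoinositide 3-kinase (-1.03 ± 0.09), were among them. Of 22 genes of ATF4 and the unfolded protein response 14 fell and 2 rose, 14 and 4 adjusted over the list alone (camera adjusted p = 0.00149, against adjusted p = 0.266 with an estimated correlation). The falls included TRIB3 (-0.80 ± 0.05), the serine synthesis enzymes PHGDH (-0.74 ± 0.05) and PSAT1 (-0.68 ± 0.05), and HERPUD1 (-0.60 ± 0.05). Interferon-stimulated genes fell in 11 of 28 and rose in 3, 13 and 3 adjusted over the list alone (camera adjusted p = 0.0246, against adjusted p = 0.426 with an estimated correlation). MX1 (-0.64 ± 0.11) and IFIT2 (-0.97 ± 0.16) were lower. Glycolytic genes rose in 12 of 22 and fell in 2, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0132, against adjusted p = 0.256 with an estimated correlation). PFKP (0.47 ± 0.04), LDHA (0.47 ± 0.05) and TPI1 (0.45 ± 0.05) were higher. With library totals the interferon call ended at camera adjusted p = 0.0536 (range over the 8 alternatives 0.00428 to 0.0536) and the glycolysis call at 0.0659 (range 0.00442 to 0.0659).

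The 2 measured immune markers, CD14 (-1.09 ± 0.07) and CSF1R (-0.29 ± 0.13, which did not pass over all genes but did with library totals, at -0.45 and adjusted p = 0.00493), were lower as a pair (camera adjusted p = 0.0435, against adjusted p = 0.197 with an estimated correlation), both adjusted over the list alone. That call ended with library totals at 0.0673, with the replicate block at 0.0534 and without docetaxel 8 h library B at 0.0613 (range over the 8 alternatives 0.0325 to 0.0673). No call was made for 13 lists. Higher and lower members were 5 and 11 of 24 for p53 targets, 3 and 5 of 11 for milk and secretory genes, 2 and 5 of 15 for the BCL2 family, 4 and 3 of 11 for PRC2 subunits, 2 and 6 of 25 for HOX genes and 5 and 6 of 24 for developmental regulators. They were 5 and 1 of 19 for antigen presentation, 2 and 5 of 20 for NF-kB cytokines, 5 and 9 of 24 for immediate early genes, 8 and 8 of 22 for YAP and SRF targets and 2 and 5 of 12 for replication histones. Fibroblast markers fell in 4 of 6 and endothelial markers in 1 of 6. Adjusted over the list alone these counts were the same, except that 10 immediate early genes were lower. The fibroblast list was called when DMSO library A, B or C was left out, at camera adjusted p = 0.0479, 0.0397 and 0.0440 (range 0.0397 to 0.144). Of the p53 targets GADD45A rose by 0.47 ± 0.05 and TP53INP1 and SESN2 fell by 1.001 and 0.60, in a line whose p53 is mutant. The proapoptotic genes BMF and BCL2L11 fell by 0.67 and 0.49, and PMAIP1 stood at 0.05 ± 0.08.

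In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3994 genes higher and 4415 lower at 8 h, of which 237 and 450 changed by at least 2-fold. Scaling by library totals alone shifted the median of all genes by -0.155 on the log2 scale and gave 2288 genes higher and 6784 lower, so small changes at 8 h depend on the scaling. The balance turned when DMSO library A, B or C was left out, to 3878 higher and 3724 lower, 3821 and 3552, and 3802 and 3656. Under that scaling antigen presentation genes had 3 higher and 6 lower and PRC2 subunits 1 higher and 5 lower, the reverse balance.

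At 24 h of docetaxel, replication-dependent histone genes and most NF-kB cytokine genes were higher than in DMSO, and DNA replication genes were lower. HIST1H1C (chromosome 6, 26055787 to 26056428), which encodes a linker histone, rose from 15.1 ± 0.0919 to 66.3 ± 4.94 CPM, a log2 fold change of 2.14 ± 0.07. CXCL8 (chromosome 4, 73740506 to 73743716), the neutrophil chemokine interleukin-8, rose from 3.26 ± 0.350 to 12.4 ± 0.571 CPM (1.92 ± 0.10). MCM2, a subunit of the replicative helicase, fell from 113 ± 6.40 to 58.9 ± 6.42 CPM (-0.95 ± 0.06). These 3 genes had adjusted p-values of at most 3.39e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

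Of the 8 named genes with the largest rises 6 were histone genes: HIST1H2BC (2.48 ± 0.12), HIST1H2BG (2.36 ± 0.13), HIST1H1C, HIST1H4H (2.01 ± 0.13), HIST2H2BE (1.91 ± 0.12) and HIST1H2BJ (1.77 ± 0.09). The others were CXCL8 and the keratin-associated KRTAP2-3 (1.87 ± 0.15), which has near-identical copies. The largest falls by the rule given above were those of the ion channel gene ASIC1 (-1.30 ± 0.12), AC240274.1 (-1.23 ± 0.09), VWA2 (-1.22 ± 0.18), the selenoprotein gene SELENOP (-1.19 ± 0.16), RIMS3 (-1.19 ± 0.06), NOMO2 (-1.18 ± 0.10), RAPH1 (-1.18 ± 0.21) and TXNDC5 (-1.18 ± 0.14). AC240274.1 lies on a scaffold not placed within a chromosome and NOMO2 has near-identical paralogs, so both are uncertain. These 16 genes had adjusted p-values of at most 0.000113 by edgeR's quasi-likelihood test.

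Of 12 replication-dependent histone genes, whose mRNA mostly lacks a poly(A) tail and which have near-identical copies, 11 rose, and all 12 did adjusted over the list alone (median 1.71; camera adjusted p = 1.85e-10, and adjusted p = 0.00268 with an estimated correlation). HIST1H2BK went from 38.7 ± 2.17 to 110.3 ± 3.70 CPM (1.51 ± 0.06) and HIST1H2BD from 16.2 ± 0.907 to 43.5 ± 3.12 CPM (1.43 ± 0.07). Replication genes fell in 26 of 30, and in 27 adjusted over the list alone (median -0.36; camera adjusted p = 8.02e-12, and adjusted p = 0.0197 with an estimated correlation). MCM6 (-0.69 ± 0.05), POLA1, the catalytic subunit of DNA polymerase alpha (-0.75 ± 0.06), and MCM3 (-0.61 ± 0.05) were among them. TOP2A, the topoisomerase of dividing cells, fell from 349 ± 9.44 to 191 ± 7.24 CPM (-0.87 ± 0.05), while the mitotic genes CCNB1 (0.59 ± 0.05), CCNB2 (0.50 ± 0.05) and KIF20A (0.42 ± 0.04) rose. MKI67 fell by 0.30 on the log2 scale.

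NF-kB cytokines and feedback genes rose in 13 of 20 and fell in 3, 14 and 3 adjusted over the list alone (median 0.37; camera adjusted p = 0.00143, and adjusted p = 0.0274 with an estimated correlation). CXCL3 rose by 1.91 ± 0.28 and IL6 by 3.01 ± 0.59 from 7 to 61 counts over the group, whereas TNFAIP2 and NFKB1 fell by 0.45 and 0.49. Of 15 fatty acid synthesis genes 12 fell, the same adjusted over the list alone (median -0.39; camera adjusted p = 1.38e-06, and adjusted p = 0.0233 with an estimated correlation). FASN fell from 2217 ± 131 to 1252 ± 113 CPM (-0.82 ± 0.06), and FADS2 (-0.66 ± 0.06) and SCD (-0.47 ± 0.05) fell too. Tubulin genes rose in 9 of 15 and fell in 1, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00181, against adjusted p = 0.247 with an estimated correlation). TUBB2A (1.04 ± 0.06), TUBB6 (0.80 ± 0.05) and TUBA1A (0.48 ± 0.06) were among the higher ones, and TUBB stood at -0.02 ± 0.05. Immediate early genes rose in 14 of 24 and fell in 5, 14 and 6 adjusted over the list alone (camera adjusted p = 0.0286, against adjusted p = 0.623 with an estimated correlation). That call ended without DMSO library C, at 0.0572, or docetaxel 24 h library A, at 0.0678 (range over the 8 alternatives 0.0115 to 0.0678). ATF3 (1.40 ± 0.08), FOSL1 (1.03 ± 0.08) and KLF4 (0.94 ± 0.09) rose, and FOS fell by 0.88. All 13 mitochondrial mRNAs were higher (median 0.61; camera adjusted p = 0.000141, against adjusted p = 0.487 with an estimated correlation).

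In lists that were not called, single stress genes rose: GADD45A, from 73.5 ± 1.17 to 159 ± 9.19 CPM (1.12 ± 0.05), DDIT3 (0.81 ± 0.09) and PPP1R15A (0.71 ± 0.07), as did the proapoptotic BBC3 (0.74 ± 0.08) and PMAIP1 (0.54 ± 0.07) and the cell cycle inhibitor CDKN1A (0.27 ± 0.07). BCL2L11 stood at 0.00 ± 0.05. KRT17 was higher than in DMSO (0.72 ± 0.05), while KRT5 stood at 0.00 ± 0.05 and the basal factor TP63 fell by 0.90. Among luminal genes EHF, PROM1 and FOXA1 fell by 0.91, 0.55 and 0.35, the growth factor AREG rose by 1.92 ± 0.21 and GATA3 stood at 0.07 ± 0.05. STAT3 and IGFBP5 fell by 0.42 and 0.91, and SOCS3 and CEBPD rose by 0.48 and 0.75. EZH2 fell by 0.21, SUZ12 by 0.34, AKT1 by 0.29 and AKT2 by 0.46. Each gene said here to rise or fall had an adjusted p of at most 0.00173 by edgeR's quasi-likelihood test.

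At 24 h 20 lists were not called. Higher and lower members were 12 and 4 of 30 for mitosis, 7 and 7 of 24 for p53 targets, 2 and 10 of 23 for luminal genes, 8 and 6 of 22 for basal genes, 8 and 9 of 26 for involution and 1 and 5 of 11 for milk and secretory genes. They were 6 and 4 of 15 for the BCL2 family, 6 and 9 of 27 for FOXO targets, 1 and 5 of 11 for PRC2 subunits, 6 and 2 of 25 for HOX genes and 8 and 3 of 24 for developmental regulators. Further counts were 9 and 5 of 28 for interferon-stimulated genes, 6 and 2 of 19 for antigen presentation, 7 and 11 of 25 for sterol genes, 3 and 7 of 22 for glycolysis, 7 and 5 of 22 for ATF4 and the unfolded protein response, 5 and 9 of 22 for YAP and SRF targets and 1 and 1 of 6 for endothelial markers. Fibroblast markers fell in 3 of 6 and immune markers in 1 of 2. Adjusted over the list alone the counts were the same for 15 of these lists. The other 5 had 10 higher and 9 lower for involution, 5 and 2 for HOX genes, 8 and 4 for developmental regulators, 7 and 12 for sterol genes and 5 and 10 for YAP and SRF targets. With upper-quartile factors the balance of involution genes turned to 9 higher and 8 lower. The luminal list was called with library totals in place of TMM factors, at camera adjusted p = 0.0458 (range over the 8 alternatives 0.0458 to 0.0864). edgeR's quasi-likelihood test called 3583 genes higher and 4044 lower, of which 397 and 153 changed by at least 2-fold. With upper-quartile factors the balance turned to 4245 higher and 3495 lower.

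Between 8 h and 24 h of docetaxel, most replication and mitotic genes and the basal keratins KRT5, KRT6A and KRT17 came down. Most histone, sterol and NF-kB cytokine genes came up. No vehicle was labelled as collected at 8 h, so a changing effect of docetaxel cannot be told apart from hours since dosing. RRM2 fell from 323 ± 12.6 to 135 ± 0.707 CPM (-1.26 ± 0.05) and AURKB from 117 ± 9.57 to 60.2 ± 2.16 CPM (-0.96 ± 0.06). HIST1H2AC, a histone of the nucleosome core, rose from 17.7 ± 1.0047 to 104 ± 4.59 CPM (2.56 ± 0.07). HMGCS1 rose from 165 ± 8.69 to 353 ± 16.9 CPM (1.09 ± 0.05), and CYP1A1 fell from 34.0 ± 2.60 to 2.28 ± 0.116 CPM (-3.90 ± 0.10). These 5 genes had adjusted p-values of at most 1.82e-11 by edgeR's quasi-likelihood test of 24 h against 8 h.

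Histone genes rose in 9 of 12 (median 2.23), the same adjusted over the list alone (camera adjusted p = 2.09e-10, and adjusted p = 0.00217 with an estimated correlation). The 5 named rises included HIST1H2BG (2.81 ± 0.14), HIST1H2BC (2.78 ± 0.13) and HIST1H2BJ (2.48 ± 0.10). Replication genes fell in 29 of 30 (median -0.59), also when adjusted over the list alone (camera adjusted p = 4.18e-23, and adjusted p = 0.00217 with an estimated correlation). Mitotic genes fell in 25 of 30 (median -0.40), with the same number adjusted over the list alone (camera adjusted p = 4.97e-14, and adjusted p = 0.0410 with an estimated correlation). CDC45 (-1.10 ± 0.05), TOP2A (-1.08 ± 0.05), CDK1 (-0.86 ± 0.05) and MKI67 (-0.89 ± 0.08) were among them. Sterol genes rose in 22 of 25, 23 adjusted over the list alone (median 0.60; camera adjusted p = 2.04e-16, and adjusted p = 0.0215 with an estimated correlation). DHCR7 (0.78 ± 0.05) and MVD (0.92 ± 0.06) rose. NF-kB cytokines rose in 13 of 20 and fell in 1, the same adjusted over the list alone (median 0.65; camera adjusted p = 6.18e-05, and adjusted p = 0.0149 with an estimated correlation). CXCL8 (2.33 ± 0.11), TNFAIP3 (1.53 ± 0.18) and ICAM1 (0.53 ± 0.05) rose.

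Basal genes fell in 13 of 22 and rose in 4, the same adjusted over the list alone (camera adjusted p = 0.000398, and adjusted p = 0.0215 with an estimated correlation). The falls included KRT6A (-2.27 ± 0.16), KRT6B (-1.11 ± 0.06), KRT5 (-0.81 ± 0.05) and KRT17 (-0.81 ± 0.05). p53 targets rose in 9 of 24 and fell in 4, 10 and 4 adjusted over the list alone (camera adjusted p = 0.00783, and adjusted p = 0.0466 with an estimated correlation). BBC3 (0.91 ± 0.08) and CDKN1A (0.61 ± 0.07) rose. HOX genes rose in 8 of 25 and fell in 1, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00664, and adjusted p = 0.0463 with an estimated correlation). HOXA5 (0.77 ± 0.12) and HOXC6 (0.67 ± 0.11) rose. Beside these 8 lists, 10 were called by camera with the preset correlation but not with an estimated one, and 9 were not called. The former included FOXO targets, with 18 of 27 higher and 2 lower, 21 and 2 adjusted over the list alone (adjusted p = 0.0531 with an estimated correlation). They also included the ATF4 and unfolded protein list, with 18 of 22 higher and 2 lower under both adjustments (adjusted p = 0.0839 with an estimated correlation), and the 13 mitochondrial mRNAs, all lower (adjusted p = 0.286 with an estimated correlation). ATF3 rose by 1.69 ± 0.08 and PIK3IP1 by 1.02 ± 0.09. The remaining 3 of the 5 named falls were IGFL1 (-2.14 ± 0.10), CYP1B1 (-1.93 ± 0.06) and OLFML3 (-1.86 ± 0.07).

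For the other 7 lists called with the preset correlation alone, higher and lower members, with the camera adjusted p of the estimated correlation in brackets, were 15 and 4 of 26 (0.0815) for involution, 8 and 2 of 15 (0.0839) for the BCL2 family, 16 and 2 of 28 (0.286) for interferon-stimulated genes and 8 and 2 of 15 (0.0848) for fatty acid synthesis. They were 2 and 12 of 22 (0.0839) for glycolysis, 12 and 1 of 24 (0.286) for immediate early genes and 5 and 13 of 22 (0.218) for YAP and SRF targets. The lists not called had 5 and 6 of 15 for tubulins, 11 and 7 of 23 for luminal genes, 2 and 2 of 11 for milk and secretory genes, 2 and 5 of 11 for PRC2 subunits, 7 and 6 of 24 for developmental regulators, 3 and 3 of 19 for antigen presentation and 3 and 1 of 6 for endothelial markers. Fibroblast markers rose in 1 of 6 and immune markers in 1 of 2. Adjusted over the list alone the counts were 9 and 2 for the BCL2 family, 16 and 3 for interferon-stimulated genes, 2 and 13 for glycolysis and 5 and 16 for YAP and SRF targets, and the others were the same. With library totals the balance of the tubulins turned to 6 higher and 4 lower.

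edgeR's quasi-likelihood test called 2947 genes higher and 3261 lower at 24 h than at 8 h, of which 441 and 98 changed by at least 2-fold. With library totals alone the median of all genes shifted by 0.131 on the log2 scale and the counts became 5392 higher and 1655 lower, and with upper-quartile factors they were 3368 and 2814.

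**Figure D1:**
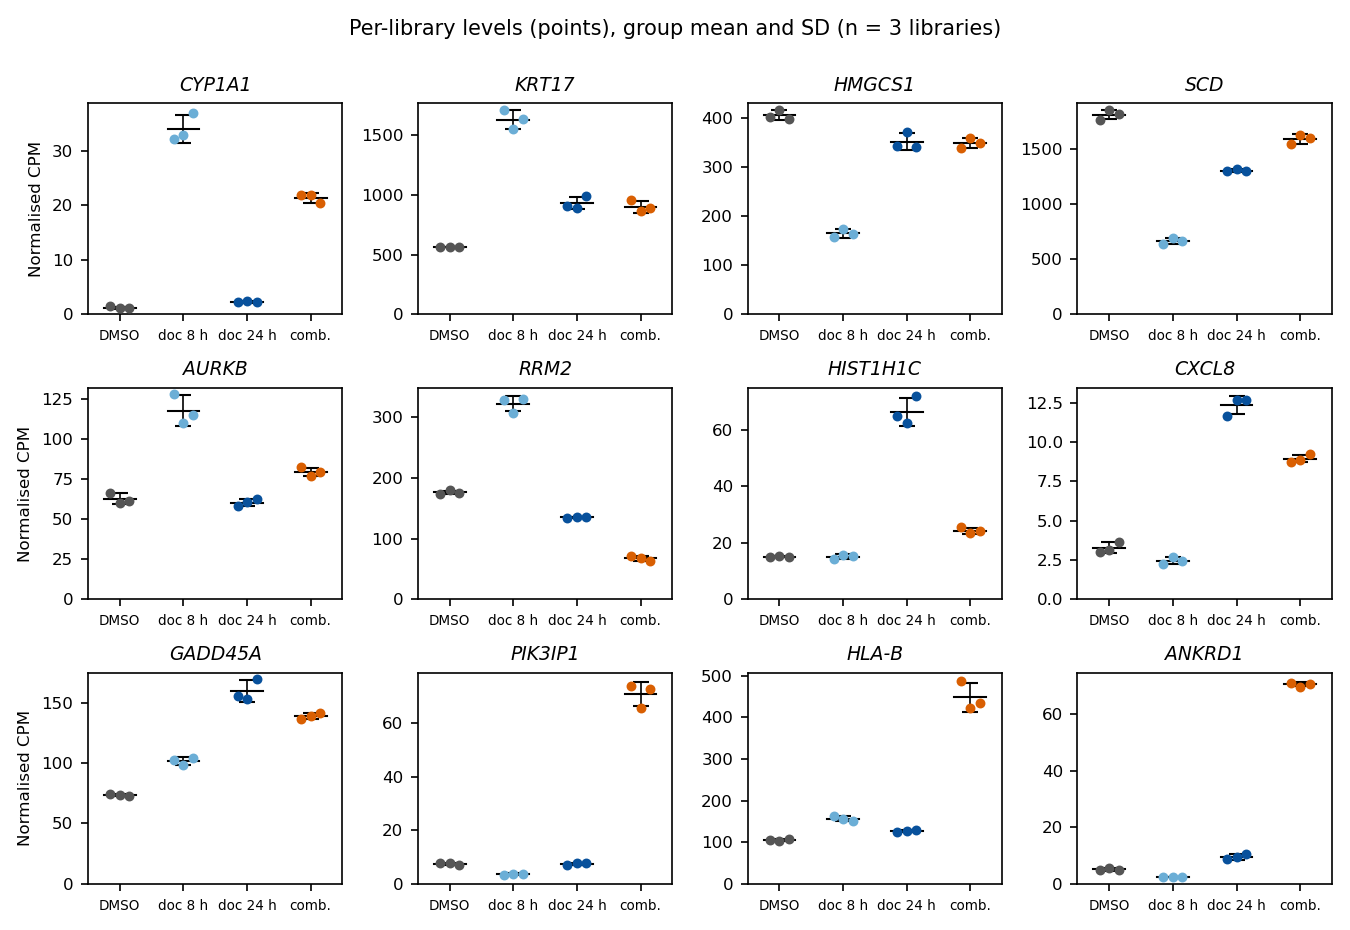
Normalised CPM of 12 genes on linear axes that start at 0, with a point for each of the 3 libraries of DMSO, docetaxel 8 h, docetaxel 24 h and the combination (comb.), and bars for the mean ± SD. HMGCS1 lies near 165 CPM at 8 h and near 353 CPM at 24 h, and CYP1A1 near 34.0 and 2.28 CPM.

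The combination of the EZH2 and AKT inhibitors changed more genes than docetaxel did: DNA replication genes fell, most genes that FOXO factors activate and most antigen presentation genes rose, and there were transcripts of genes that had none or nearly none in DMSO. PIK3IP1 (chromosome 22, 31281593 to 31292534) rose from 7.56 ± 0.326 to 70.7 ± 4.40 CPM, a log2 fold change of 3.22 ± 0.07. HLA-B (chromosome 6, 31269491 to 31357188), a class I antigen presenting gene, rose from 106 ± 1.83 to 448 ± 35.1 CPM (2.08 ± 0.05). RRM2 fell from 176 ± 3.14 to 67.4 ± 4.50 CPM (-1.38 ± 0.05). These 3 genes had adjusted p-values of at most 3.56e-16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TENM3 (chromosome 4, 182143987 to 182803024), which encodes a teneurin, an adhesion protein, had 0 counts over the 3 DMSO libraries and 38.8 ± 0.496 CPM in the combination, at least 1407-fold higher against a floor of 3 counts over the group. Such bounds, and the counting intervals, cover counting error only.

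The 8 named rises were ordered by fitted folds, which puts genes with 0 counts in DMSO at the top, so they need not be the 8 largest rises. Of them 7 had 0 counts in DMSO, and their folds are lower bounds against the same floor of 3 counts. MMP13 (0.0288 CPM in DMSO and 28.8 CPM in the combination), chosen after its values were seen, is not among the 8 though its ratio of CPM lies above most of these bounds. Beside TENM3 the 7 were the gap junction gene GJA1 (at least 471-fold), SPANXB1 (at least 302-fold, with near-identical copies), AOC1 (at least 280.4-fold), the matrix metalloproteases MMP12 (at least 266-fold) and MMP3 (at least 264-fold), and PRR9 (at least 220.1-fold). The collagenase gene MMP1 had 1 count over the DMSO libraries and 1967 in the combination, a ratio of 2282 with a 95% counting interval from 409 to 9.02e+04. The largest falls by the same rule were those of STAC2, from 35.1 ± 1.28 to 1.55 ± 0.252 CPM (-4.49 ± 0.09), the sodium chloride cotransporter SLC12A3 (-3.43 ± 0.15), PCDH9 (-2.67 ± 0.07), BBOX1 (-2.66 ± 0.17), the interferon-induced GBP1 (-2.54 ± 0.10), the hair keratin KRT38 (-2.45 ± 0.15), U2AF1 (-2.34 ± 0.44) and ASB3 (-2.27 ± 0.13). U2AF1 has a near-identical copy in the reference and varied among the DMSO libraries (11.5 ± 10.2 CPM), so it is uncertain. All 16 had adjusted p-values of at most 6.67e-05 by edgeR's quasi-likelihood test.

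Replication genes fell in 28 of 30 and rose in 1, the same adjusted over the list alone (median -0.90; camera adjusted p = 5.33e-13, and adjusted p = 0.0294 with an estimated correlation). The transcription factor E2F1 fell from 110.3 ± 2.26 to 45.7 ± 1.55 CPM (-1.27 ± 0.05), the phosphatase CDC25A by 1.53 and MCM10 by 1.38 on the log2 scale. Mitotic genes went both ways, with 13 of 30 higher and 7 lower and no call: HMMR (0.63 ± 0.05) and UBE2C (0.63 ± 0.06) rose and cyclin CCNA2 fell by 0.51. The inhibitor CDKN1A rose from 40.6 ± 2.45 to 99.8 ± 3.65 CPM (1.30 ± 0.06), and GADD45A (0.92 ± 0.05), BBC3 (1.30 ± 0.07) and PHLDA3 (0.82 ± 0.07) rose, in a list of p53 targets that was not called. The proapoptotic genes HRK (1.34 ± 0.08), BMF (0.68 ± 0.08) and PMAIP1 (0.46 ± 0.07) rose and BCL2 fell by 0.76.

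FOXO targets rose in 19 of 27 and fell in 6, 19 and 8 adjusted over the list alone (median 0.44; camera adjusted p = 0.00588, against adjusted p = 0.305 with an estimated correlation). The pyruvate dehydrogenase kinase PDK4 went from 0.194 ± 0.0117 to 8.45 ± 0.349 CPM (5.42 ± 0.22), and CDKN1C (2.21 ± 0.12), cyclin CCNG2 (1.11 ± 0.05) and the insulin receptor substrate IRS2 (1.27 ± 0.09) rose. Antigen presentation genes, whose HLA members are polymorphic near-copies, rose in 14 of 19 and fell in 2, the same adjusted over the list alone (median 0.94; camera adjusted p = 0.000144, against adjusted p = 0.210 with an estimated correlation). HLA-F (2.16 ± 0.08) and HLA-C (1.26 ± 0.06) were among them. Mitochondrial counts were also higher in these libraries, as were all 13 mitochondrial mRNAs (median 0.88; camera adjusted p = 0.00111, against adjusted p = 0.503 with an estimated correlation). EZH2 itself fell from 111 ± 2.72 to 67.4 ± 3.95 CPM (-0.73 ± 0.05), EED by 0.43 and SUZ12 by 0.60 on the log2 scale. AKT1 and AKT2 fell by 0.32 and 0.28.

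Developmental regulators that commonly carry the PRC2 mark rose in 15 of 24 and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.0304, against adjusted p = 0.210 with an estimated correlation). The guidance gene SLIT2 went from 0.208 ± 0.178 to 6.66 ± 0.126 CPM (5.01 ± 0.31), BMP2 (1.24 ± 0.09) and BMP4 (1.06 ± 0.08) rose and DLX3 fell by 1.11. HOX genes rose in 13 of 25 and fell in 2, 14 and 2 adjusted over the list alone (camera adjusted p = 0.0394, against adjusted p = 0.210 with an estimated correlation), among them HOXB7 (0.96 ± 0.09) and HOXB9 (3.36 ± 0.39). This call ended without DMSO library A, at 0.0621, or combination library B, at 0.0658 (range over the 8 alternatives 0.0305 to 0.0658). Basal genes rose in 13 of 22 and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.0394, against adjusted p = 0.210 with an estimated correlation). There were rises of vimentin (VIM, 1.87 ± 0.07), ITGB4 (1.24 ± 0.05), LAMB3 (1.204 ± 0.06) and KRT17 (0.68 ± 0.05) and a fall of KRT5 by 0.79. The basal call ended with the replicate block (0.0539) and without DMSO library A (0.0621), combination library A (0.0535) or combination library B (0.0503), with a range of 0.0377 to 0.0621. Luminal genes went both ways without a call, with GATA3 (0.75 ± 0.05) and TBX3 (4.25 ± 0.28) higher and FOXA1, CD24 and SPDEF lower, at -0.66, -1.09 and -1.07.

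Immediate early genes rose in 14 of 24 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0304, against adjusted p = 0.504 with an estimated correlation). Examples were FOSL1 (2.08 ± 0.08) and DUSP5 (1.18 ± 0.06) higher and MYC lower (-0.95 ± 0.05). Without combination library C the call ended, at 0.0716 (range over the 8 alternatives 0.00709 to 0.0716). Endothelial markers rose in 4 of 6, the same adjusted over the list alone (camera adjusted p = 0.0304, against adjusted p = 0.210 with an estimated correlation). They were KDR (0.71 ± 0.09), CDH5 (1.89 ± 0.28), ESAM (0.47 ± 0.09) and ERG, which had 1 count over the DMSO libraries and 182 in the combination (ratio 211, 95% counting interval 37.4 to 8386). YAP and SRF targets were not called as a list, but ANKRD1 went from 5.13 ± 0.423 to 70.6 ± 0.710 CPM (3.79 ± 0.08), and AXL (3.14 ± 0.15) and CTGF (1.28 ± 0.07) rose. Tubulin genes split, with TUBA1A (2.43 ± 0.06) and TUBB2B (2.82 ± 0.09) higher and TUBA1B lower (-0.58 ± 0.06). The chemokine gene CCL2 rose from 0.264 ± 0.0499 to 10.9 ± 0.686 CPM (5.33 ± 0.20) and the milk-associated WFDC2 from 0.546 ± 0.257 to 10.4 ± 0.882 CPM (4.21 ± 0.20). STAT3 fell by 0.47 on the log2 scale, SOCS3 rose by 1.12 ± 0.08 and the cathepsin CTSB rose by 1.199 ± 0.05.

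In the combination 18 lists were not called. Higher and lower members were 13 and 7 of 30 for mitosis, 12 and 7 of 24 for p53 targets, 8 and 5 of 15 for tubulins, 8 and 10 of 23 for luminal genes and 13 and 9 of 26 for involution. They were 5 and 2 of 11 for milk and secretory genes, 7 and 7 of 15 for the BCL2 family, 2 and 7 of 11 for PRC2 subunits, 7 and 8 of 28 for interferon-stimulated genes and 10 and 6 of 20 for NF-kB cytokines. Further counts were 11 and 6 of 25 for sterol genes, 3 and 10 of 15 for fatty acid synthesis, 4 and 12 of 22 for glycolysis, 8 and 9 of 22 for ATF4 and the unfolded protein response, 9 and 7 of 22 for YAP and SRF targets, 2 and 1 of 6 for fibroblast markers and 1 and 1 of 2 for immune markers, and 3 of 12 histone genes rose. Adjusted over the list alone 8 mitotic genes and 8 p53 targets were lower, and the other counts were the same. With upper-quartile factors the balance of interferon-stimulated genes turned to 8 higher and 6 lower. The fibroblast marker LUM, which encodes lumican, had 0 counts in DMSO and was at least 152-fold higher, while COL1A1 fell by 0.26. Of the immune markers CSF1R rose by 2.50 ± 0.10 and CD14 fell by 0.96. The glycolysis list was called with library totals, at camera adjusted p = 0.0389, and without DMSO library C (0.0448) or combination library A (0.0367), with a range of 0.0367 to 0.0938 over the 8 alternatives. edgeR's test called 5579 genes higher and 5578 lower, of which 2151 and 480 changed by at least 2-fold. With upper-quartile factors 6644 were higher and 4441 lower, and with library totals 5170 and 6013, so the even balance depends on the scaling. The identity of the cells in these libraries was not checked by genotype, since the reads were not used here.

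**Figure D2:**
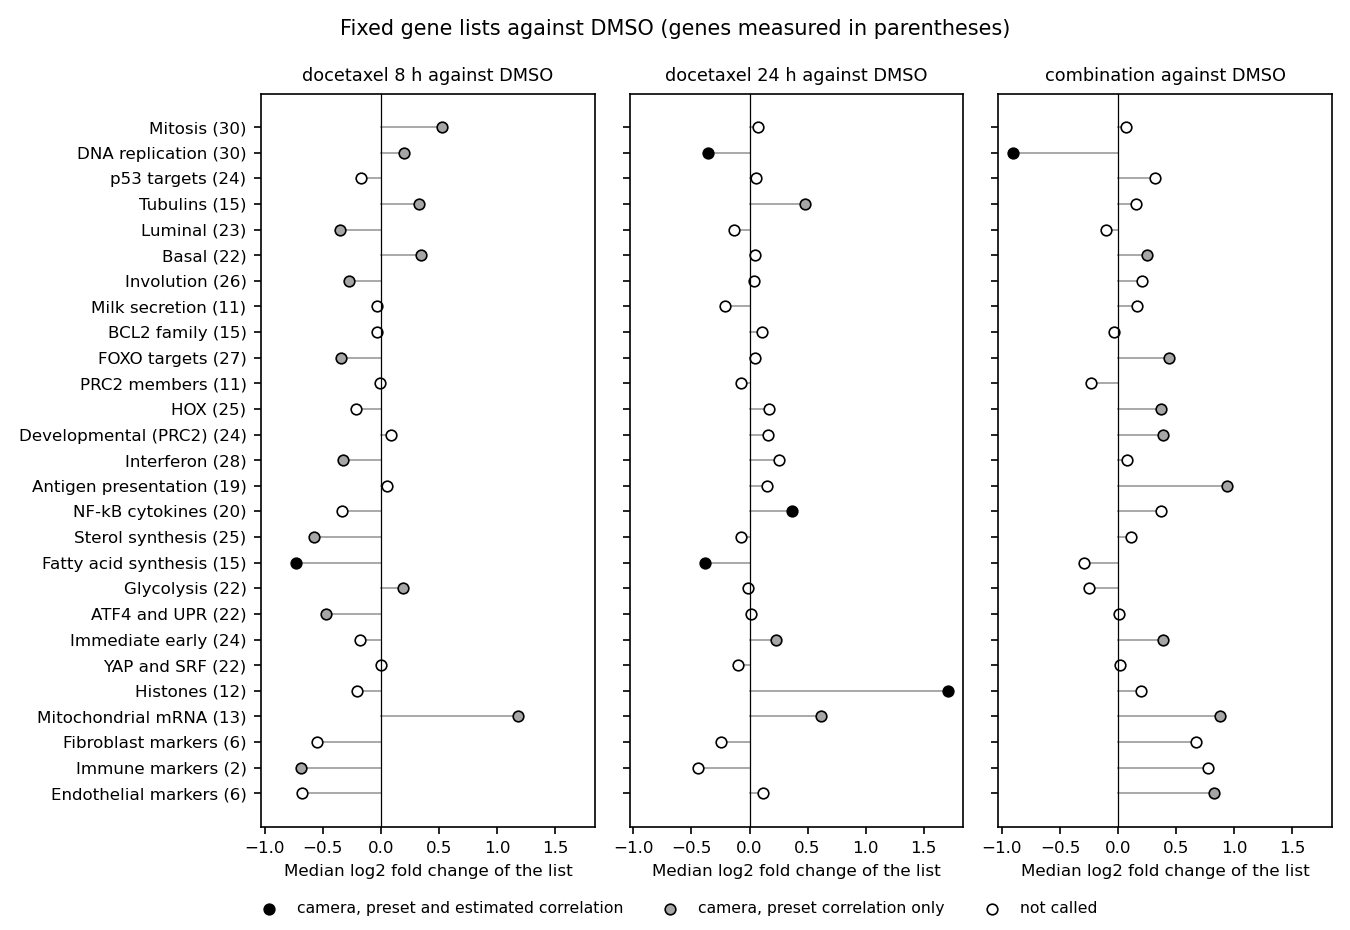
Median log2 fold change of the measured genes of each fixed list in the 3 comparisons with DMSO, with black points for lists called by camera with both the preset and the estimated correlation, grey points for the preset correlation alone and white points for lists not called. The replication list lies at 0.20 at 8 h of docetaxel, at -0.36 at 24 h and at -0.90 in the combination.

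The gene with the smallest adjusted p in the combination was FKBP9P1, an unprocessed pseudogene of the chaperone gene FKBP9 on chromosome 7, 55681074 to 55713252, minus strand, singled out after its values were seen. It rose from 2.16 ± 0.258 to 1154 ± 14.8 CPM (log2 fold change 9.04 ± 0.08; edgeR adjusted p = 1.95e-28), whereas FKBP9 stood at 0.06 ± 0.05 and did not pass. With upper-quartile factors FKBP9 passed, at 0.15 (adjusted p = 0.00751). EGFR, the growth factor receptor gene on the same arm at 55019021 to 55211628, rose by 0.35 ± 0.08. Within 1 Mb of FKBP9P1 the other 26 genes had a median log2 fold change of 0.242, with 12 higher and 5 lower. The 4 nearest, named after their values were seen, all rose: AC091812.1, from 3 counts over the DMSO libraries to 546 (ratio 211, 95% counting interval 71.9 to 1027), TUBBP6, from 1 to 67 (ratio 77.7, 13.5 to 3116), AC091812.3 (1.82) and AC091812.2 (1.59).

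**Figure D3:**
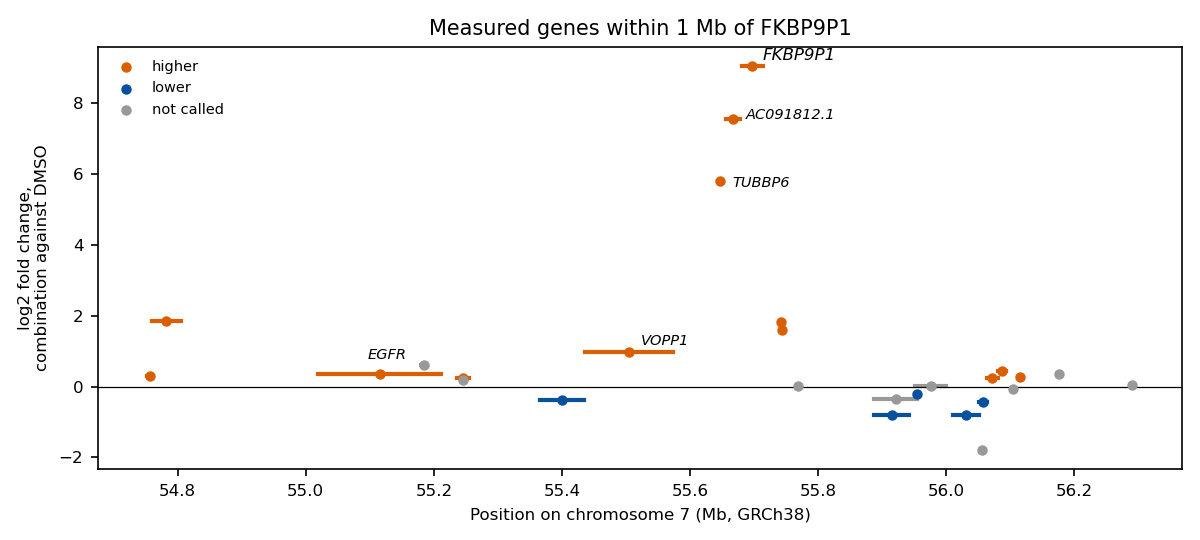
Log2 fold change in the combination against DMSO of genes near FKBP9P1, by position on chromosome 7 in Mb (GRCh38), with orange points for genes called higher, blue for lower and grey for genes not called. FKBP9P1 lies at 9.04 and EGFR at 0.35. The heights of AC091812.1 and TUBBP6 are fitted values that rest on 3 and 1 DMSO counts.

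Set against docetaxel at 24 h, the combination had most FOXO targets and antigen presentation genes and the hemidesmosome genes ITGB4 and LAMB3 higher, and most histone and replication genes lower. PIK3IP1 rose from 7.47 ± 0.458 to 70.7 ± 4.40 CPM (3.24 ± 0.07) and ITGB4, an integrin subunit of hemidesmosomes, from 373 ± 10.2 to 1202 ± 40.0 CPM (1.69 ± 0.05). HIST1H1C fell from 66.3 ± 4.94 to 24.2 ± 1.08 CPM (-1.45 ± 0.06). These 3 genes had adjusted p-values of at most 5.56e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 2 treatments also differed in plate size, the cells of the combination had been held in tazemetostat or DMSO and passaged over the 5 days before the 24 h, and the serum of the docetaxel cultures is not stated, so the comparison is of whole protocols.

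Histone genes fell in 10 of 12, the same adjusted over the list alone (median -1.41; camera adjusted p = 5.21e-05, and adjusted p = 0.0339 with an estimated correlation), and this was the 1 list called with both correlations. Replication genes fell in 26 of 30 and rose in 3, the same adjusted over the list alone (camera adjusted p = 1.14e-07, against adjusted p = 0.0690 with an estimated correlation). CDC25A (-1.39 ± 0.06) and RRM2 (-1.002 ± 0.05) fell. FOXO targets rose in 18 of 27 and fell in 4, 18 and 5 adjusted over the list alone (camera adjusted p = 0.000831, against adjusted p = 0.253 with an estimated correlation). Antigen presentation genes rose in 15 of 19 and fell in 1, the same adjusted over the list alone (camera adjusted p = 5.21e-05, against adjusted p = 0.253 with an estimated correlation). LAMB3 (1.55 ± 0.06), HLA-B (1.81 ± 0.05), IRS2 (1.12 ± 0.09), ERBB3 (0.61 ± 0.05), CDKN1A (1.03 ± 0.06) and BMF (0.92 ± 0.08) rose. EZH2 and KRT5 fell by 0.51 and 0.79, and PLK1 stood at 0.02 ± 0.05. The 5 named rises, again ordered by fitted folds that put genes with 0 counts at the top and which so need not be the 5 largest, were GJA1 (at least 486-fold), HAPLN1 (at least 288-fold), MMP12 (at least 274-fold) and MMP3 (at least 272-fold), with 0 counts at 24 h of docetaxel, and TENM3, with 1 count there (ratio 4351, 95% counting interval 780.4 to 1.72e+05). The 5 named falls were STAC2 (-3.96 ± 0.09), the hyaluronan synthase HAS3 (-2.75 ± 0.20), HIST1H2BG (-2.71 ± 0.14), BBOX1 (-2.49 ± 0.17) and HIST1H2BC (-2.38 ± 0.12). The other 23 lists were not called. Higher and lower members were 9 and 9 of 30 for mitosis, 14 and 10 of 24 for p53 targets, 6 and 8 of 15 for tubulins, 8 and 8 of 23 for luminal genes, 13 and 6 of 22 for basal genes, 12 and 9 of 26 for involution and 6 and 1 of 11 for milk and secretory genes. They were 5 and 5 of 15 for the BCL2 family, 4 and 7 of 11 for PRC2 subunits, 12 and 3 of 25 for HOX genes, 14 and 5 of 24 for developmental regulators, 11 and 5 of 28 for interferon-stimulated genes, 4 and 12 of 20 for NF-kB cytokines and 15 and 2 of 25 for sterol genes, and 9 and 4 of 15 for fatty acid synthesis, 6 and 12 of 22 for glycolysis, 6 and 11 of 22 for ATF4 and the unfolded protein response, 14 and 7 of 24 for immediate early genes, 10 and 7 of 22 for YAP and SRF targets and 1 and 1 of 2 for immune markers. Mitochondrial mRNAs rose in 8 of 13, fibroblast markers in 3 of 6 and endothelial markers in 4 of 6. Adjusted over the list alone there were 9 and 5 interferon-stimulated genes, 5 and 12 NF-kB cytokines and 6 and 13 glycolytic genes, and the other counts were the same. The fibroblast list was called without docetaxel 24 h library A, at camera adjusted p = 0.0366 (range over the 8 alternatives 0.0366 to 0.104). edgeR's test called 5709 genes higher and 5631 lower, of which 2113 and 564 changed by at least 2-fold, and with upper-quartile factors 6258 were higher and 4950 lower, against 5535 and 5761 with library totals.

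The responses to docetaxel at 24 h and to the combination overlapped. Against DMSO 1398 genes were higher in both and 2234 were lower in both, where independent lists of the same sizes would share 1124 and 1269, and 1686 of the 5318 genes called in both went opposite ways. MCM2, FASN and STAT3 were lower in both, and GADD45A, KRT17 and CXCL8 were higher in both. Over the 17780 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.310 and a Spearman correlation of 0.293. Both comparisons use the same 3 DMSO libraries, and 20 simulations of unchanged groups against those controls gave a mean Pearson correlation of 0.492, between 0.471 and 0.520. The observed covariance was 0.191, the simulated mean was 0.0178 and their difference 0.173. Simulated comparisons called 0.1 genes in both on average. The simulated correlation is that of noise alone, so it is no benchmark for groups that changed. The difference in covariance of 0.173 lies beyond what the spread of the shared controls gave in the simulations. With 3 controls no split leaves 2 on each side. A shift common to the 3 DMSO libraries, whose hours and medium are not stated, was not simulated and may add to the overlap.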

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

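Of the tests weighed here, the summed histone level and the replication genes were chosen only after the histone result was seen. The results below were singled out because docetaxel-treated cells differed between the time points, by edgeR's test of 24 h against 8 h. Against DMSO, 262 genes were higher at 8 h and lower at 24 h, and 159 were lower at 8 h and higher at 24 h, each with the change between the time points called as well. Replication genes had a median change of -0.59 (log2) between the time points, from 0.20 at 8 h to -0.36 at 24 h. CXCL8, the chemokine interleukin-8, changed by 2.33, from -0.41 to 1.92, and TNF, a cytokine of the same NF-kB programme, by 2.58, from -1.25 to 1.32. The linker histone HIST1H1D changed by 3.51 between the time points, from -1.54 to 1.97. The core histones HIST2H2BE (2.56), HIST1H2AC (2.56) and HIST1H2BD (2.32) also went from below DMSO to above it. The 8 h and 24 h libraries share their DMSO controls, and the hours of those controls are not stated. With no vehicle labelled as 8 h, a changed effect of docetaxel cannot be told apart from hours since dosing or medium.

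Replication-dependent histone mRNAs mostly lack a poly(A) tail, so their rise in poly(A)-selected libraries at 24 h (list median 1.71, 95% bootstrap interval 1.13 to 2.08) was weighed against 3 explanations. Carry-over of RNA without a tail would lift other such RNAs alike, if it did not depend on their length. The 40 small structural RNAs measured had a median of 0.391 (0.324 to 0.578), under 0.856, which is 0.5 times the histone median. Of them 6 were called higher and 0 lower, and their summed CPM rose 1.37-fold, so carry-over may still play a part. Reads moving between near-identical copies would leave their sum unchanged, but the summed CPM of 45 histone genes rose 2.50-fold, from 232 in DMSO to 580 at 24 h, with 161 at 8 h and 251 in the combination. More cells in S phase would raise replication genes, whose median was -0.356 (-0.445 to -0.251). The summed CPM and the replication genes argue against moving reads and against more cells in S phase as the whole cause. The small structural RNAs argue against carry-over as the whole cause only if it did not depend on length, which was not tested. A candidate explanation that stays open is that docetaxel-treated cells at 24 h make histone transcripts with a poly(A) tail, a hypothesis formed from these data that was not tested. Reads over the ends of histone transcripts would decide it and were not used here.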

How the results depend on the processing

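The authors' size factors and the fit without mitochondrial genes were chosen only after the results were seen, and the other alternatives were planned. For the 5 comparisons, genes called in the result as reported remained called in the same direction in at least 74.1% of cases under each of the 18 settings run for a comparison beside the fold threshold, and no called gene was called in the opposite direction. The counts of genes moved by more than 1.5 times under library totals only and under the fold threshold. With upper-quartile factors the balance turned to more genes higher at 24 h (4245 and 3495 lower) and at 24 h against 8 h (3368 and 2814). At 8 h it turned without DMSO library A (3878 and 3724), B (3821 and 3552) or C (3802 and 3656). The even balance of the combination moved to 6644 higher and 4441 lower with upper-quartile factors and to 5170 and 6013 with library totals.

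With library totals only, 2288 genes were higher and 6784 lower at docetaxel 8 h, and 5392 were higher and 1655 lower at 24 h against 8 h. That scaling shifted the median of all genes by -0.155 and 0.131, which by its construction moves small changes together. A threshold of an absolute log2 fold change of at least 1 left by its construction fewer genes: 237 higher and 450 lower at 8 h, 397 and 153 at 24 h, 441 and 98 at 24 h against 8 h, 2151 and 480 in the combination, and 2113 and 564 in the combination against docetaxel 24 h. Without mitochondrial genes 3999 genes were higher and 4393 lower at 8 h.

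The letters A, B and C did not pair the libraries: after group means were taken off, same-letter correlations lay between -0.134 and 0.143, 1 of 18 pairs was above 0.1, and 6 of 12 libraries matched best with their own letter. With the replicate block 4021 genes were higher and 4469 lower at 8 h, 3630 and 4137 at 24 h, 3001 and 3368 at 24 h against 8 h, 5586 and 5632 in the combination, and 5739 and 5664 in the combination against docetaxel 24 h.

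Leaving out each library in turn gave 3545 to 3878 higher and 3552 to 4279 lower at 8 h, 2826 to 3394 and 3306 to 3841 at 24 h, and 2345 to 2686 and 2829 to 3119 at 24 h against 8 h. For the combination it gave 5215 to 5420 and 5143 to 5378, and against docetaxel 24 h 5440 to 5637 and 5093 to 5407. The correlation of the responses to docetaxel 24 h and the combination lay between 0.255, without docetaxel 24 h library C, and 0.380, without DMSO library A, against 0.310 with all libraries; the cause was not tested.

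Of the gene lists, 52 list calls over the 5 comparisons became 15 with camera's estimated correlation and 112 with fry, which does not compare a list with other genes. They were 49 with library totals, 50 with the replicate block and 50 to 53 with a library left out. Values of single genes and lists were also compared under the settings chosen in advance. Of them 12450 kept their side of the threshold, 146 fell short of it and 100 newly passed it. Under the alternatives chosen after seeing the data these numbers were 1401, 1 and 2. A change of direction was counted only where the value passed the threshold in at least 1 of the fits compared. Under fry the tubulin list in the combination against docetaxel 24 h had the opposite direction to camera's, with an adjusted p of 0.0221; the cause was not tested. At these depths of 29820617 counts and more, a gene below 0.1 CPM has few counts per library, so its fold is uncertain. Where a group had 0 counts the fold is a bound.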

Other observations

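Of the tests below, the fibroblast, SMAD4, summed FKBP9 and 8 h vehicle tests, and the genes named here outside the rule, were chosen only after the results were seen. The combination gave more than 5 CPM to 36 genes that lay below 0.1 CPM in DMSO. Among them were TENM3 (38.8 CPM in the combination), the collagenases MMP13 (28.8 CPM) and MMP1 (20.97 CPM), the small heat shock protein HSPB8 (0.0584 CPM in DMSO, 25.0 CPM in the combination, 0.613 CPM at 24 h of docetaxel), SHISA2 (17.8 CPM), GJA1 (13.0 CPM) and the chromatin organiser SATB1 (12.7 CPM).

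CYP1A1, the reporter of aryl hydrocarbon receptor activity, was higher in the combination than in DMSO as well as at 8 h of docetaxel, by 4.08 ± 0.11 (log2), at 21.4 CPM. TIPARP and AHRR, which that receptor also induces and which repress it, rose by 0.79 and 0.53, whereas CYP1B1 fell by 0.47.

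The fall of sterol genes at 8 h of docetaxel had a list median of -0.58 (95% bootstrap interval -0.73 to -0.38). A trend with GC content or gene length over 17689 genes explained 6.25% of the variance, and after it was taken off the list median was -0.477 (-0.72 to -0.379). The median stayed below the bound of -0.4 set for it beforehand, so the trend as fitted did not take off the whole fall. The upper end of the interval lay above that bound, as it did before the trend was taken off (-0.38). The test also asked for this upper end to lie below the bound, so it was counted as undecided. A part played by this trend cannot be told apart from a treatment effect. The other explanation, medium, plate or hours since dosing, needs vehicle libraries at 8 h, of which there were 0, so it stays open too. That docetaxel itself lowers these genes early is a hypothesis that was not tested apart from these explanations, and vehicle libraries at 8 h would decide it.

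The 36 genes switched on in the combination were weighed against 3 explanations. Fibroblasts in the wells would bring collagens along with LUM, but the summed CPM of COL1A2 and COL3A1 was 0.0409 times that of LUM in the combination (16 against 392 counts). A criterion written earlier, the sum of 3 collagens, gave 21.6 CPM in DMSO and 18.2 CPM in the combination (0.843-fold), and it was replaced because COL1A1 is expressed in DMSO. That genes at the floor can only rise would apply to docetaxel alike, but it brought 0 of 441 genes above 5 CPM at 24 h. These 441 were the genes below 0.1 CPM in DMSO among those that passed the low-count filter. They passed it through counts in other groups, so they are not all the genes at the floor. Cells of a line with an intact SMAD4 gene would raise SMAD4, whose log2 fold change of -0.18 ± 0.45 had an upper 95% limit of 0.865. That limit meets the bound of under 1 which was set after the result was seen, and it was at first read as evidence against this explanation. The reading was then changed, because 19 and 25 counts are near the floor and too few to decide, so the explanation stays open.

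FKBP9P1, which is not among the 36 and went from 2.16 to 1154 CPM, was weighed against 2 further explanations. Reads of FKBP9 assigned to the pseudogene would leave the sum of both unchanged, but it rose 8.95-fold. A rise of the whole region would lift its neighbours alike, but the other 26 genes within 1 Mb had a median of 0.242 (-0.0297 to 0.387). The 4 nearest, named after their values were seen, all rose with it: AC091812.1, from 3 counts over the DMSO libraries to 546 (ratio 211, 95% counting interval 71.9 to 1027), TUBBP6, from 1 to 67 (ratio 77.7, 13.5 to 3116), AC091812.3 (1.82) and AC091812.2 (1.59). The next nearest, PSPHP1, stood at 0.02 and did not pass, and farther away VOPP1 rose by 0.98 and PSPH fell by 0.82. A rise over a shorter stretch around FKBP9P1 therefore stays open. Loss of PRC2 repression, AKT inhibition, days of passaging in tazemetostat and a subpopulation that grew out under it may each explain the switched-on genes, and without single-drug arms they stay open. A different subline or a mislabelled set of libraries also stays open and was not tested. It would change the meaning of every combination value, and genotypes from the reads, which were not used here, would decide it. Beside the 36 genes switched on, 0 genes went from above 5 CPM in DMSO to below 0.1 CPM in the combination. That count does not decide it, since a subline need not lose genes.

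Each comparison of 3 with 3 libraries allows 10 splits, so the share of splits with a result as large cannot be under 0.05. For docetaxel 8 h against DMSO 1 split, the real one, called 8412 genes in a fit of the 6 libraries, and the highest other called 1 by edgeR and 0 by limma-voom (up to 201 at an unadjusted p under 0.05). The real split was also the only 1 of the 10 with as many calls for docetaxel 24 h against DMSO (8044), 24 h against 8 h (5585), the combination against DMSO (11359) and the combination against docetaxel 24 h (11127). There the highest other split called 0 genes by edgeR and 0 by limma-voom, with up to 317, 667, 85 and 215 genes at an unadjusted p under 0.05.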
